A study of Drosophila melanogaster with 3 samples.

How the data were processed

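Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 10 hours from a transgenic line that expresses Stwl (stonewall) with GFP fused to its C-terminus. Per the labels, an antibody against GFP was used, chromatin was sheared by sonication to 200 to 800 bp, and 3 biological replicates were made. Only 1 group is labelled, so no comparison between conditions was made and the replicates were compared with each other.

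Per the deposited text files that accompany the lists, each of the 3 replicate peak lists came from the alignments of that library and of a control library, a pooled list came from the alignments of all 3 libraries and the control, and a list of peaks that pass the irreproducible discovery rate (IDR) was derived from the replicate lists and the pooled list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The genome build is dm6, per the labels. Each deposited list gives, per peak, a signal value set by the authors' caller, the −log10 of a q-value, and the distance of the summit from the peak start. The authors' signal values have a scale of their own in each list and were used to rank, describe or filter peaks, in the comparison of promoter and other summits within the IDR list, in rank correlations between replicates, and in checks of how the replicates add up and of the stwl locus. Each replicate list and the pooled list holds 30000 peaks, so list lengths carry no information on binding. All 7241 peaks of the IDR list are peaks of the pooled list with the same signal value, and they are the 7241 strongest of that list. Read depth is unknown, so no interval rests on it; the 95% intervals given for shares of summits or genes (Wilson) and for folds cover counting error only, and summits are not independent replicates.

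Coordinates are those of dm6, counted from 1. The reference is the same Release 6 assembly: the end of every pooled peak on the main arms lay within the length of its arm. Genes, transcription start sites (TSSs), exons and transposable elements came from the Ensembl annotation BDGP6.54. The analysis was restricted to 2L, 2R, 3L, 3R, 4 and X, with 133.6 Mb of known bases and 13945 protein-coding genes. Peaks were represented by their summits, since 7241 summits lie in 7097 intervals.

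A summit within 500 bp of a TSS was called a promoter summit, and a gene was called bound if an IDR summit lay within 500 bp of one of its TSSs. The same summit can make several genes bound, and which of them it acts on was not tested. Replicate lists were compared through their 7241 strongest summits, with summits within 150 bp called shared, against 1000 circular shifts of 1 list along each arm. Shares of summits were tested against shares of bases, and densities against each other, by two-sided exact binomial tests. The 20 gene lists, 5 RNA gene classes and head-to-head promoters (2667 pairs of protein-coding genes with divergent TSSs up to 1000 bp apart, against 5471 genes with no TSS of another gene within 2000 bp) were tested by two-sided Fisher's exact tests, with odds ratios and Woolf intervals. The 12 sequence motifs were searched on both strands within 100 bp of each summit and in windows of the same size centred 1000 bp to either side, and summit and upstream flank were compared by an exact McNemar test. The upstream flank of these tests is the window at the lower coordinate, whatever the strand of the gene. Motif folds against flanks use the mean share of both sides, so test and fold do not rest on the same windows. Strand-collapsed 8-mers were compared between summit and flank windows by a Fisher-type hypergeometric test with the smaller tail doubled. Median signal values at promoter and other summits were compared by a two-sided permutation test with 100000 resamples. Families of tests were adjusted by the Benjamini-Hochberg method at 0.05. P-values under 1e-300 are given as below that value.

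The lists, motifs, tests and most alternatives were fixed before the data were examined. Motif and list names carry textbook knowledge and were not learned from these data. Gene symbols of the lists were matched to the annotation by symbol or unique synonym, and 5 symbols were matched by hand. Every listed gene was found. The genes named in the text are those nearest to the 12 strongest IDR peaks, up to 3 members of each list with the strongest promoter peaks (or the first 2 in alphabetical order where no member was bound), and stwl and bam. Genes of other kinds that are named were chosen after their values were seen, and this is said beside them.

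Alternatives covered the stricter part of the IDR list by signal, a consensus of the 3 replicates made from their strongest summits, leaving out each replicate in turn (the summits shared by the strongest of the other replicates, which thus also replaces the IDR list by a consensus), other distances to the TSS, other distances between shared summits, other numbers of peaks, other boundaries of proximal sequence, lower-ranked pooled peaks as background, a narrower motif window and 6-mers. Added after seeing the data were the IDR list without summits within 50 kb of stwl, a single summit per interval, head-to-head genes scored by their own TSSs, promoters without a peak of the pooled list as motif background, and gene lists restricted to isolated genes.

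The tests were run on simulated data. In 10 sets of 7241 random summits, 0 of 200 list tests and 0 of 120 motif tests passed the threshold. These summits were spread evenly over the arms, so the sets do not give the rate of false calls for summits that gather at promoters. All 3 lists planted at 80% of their members were recovered, as were all 770 windows given a DRE, and the planted sequence ranked 1 among 32896 8-mers. The windows were searched for the sequence written into them, so their recovery only checks that the search runs. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Reads, coverage and the control library were not analysed here.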

Results

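Binding of Stwl, a nuclear protein with a MADF domain that is known for its role in the maintenance of female germline stem cells, was mapped in whole embryos aged 0 to 10 hours. The protein carried GFP at its C-terminus and was precipitated through GFP. The 3 biological replicates gave 1 peak list each, and 7241 summits of the pooled data passed the IDR threshold. All values below rest on these lists, and the signal value of a peak is the authors' own. Coordinates are those of dm6.

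The first question was how far the replicates found the same sites. Among the 7241 strongest summits of each list, replicates 1 and 2 shared 74.9%, replicates 1 and 3 shared 79.2% and replicates 2 and 3 shared 76.3% within 150 bp, a mean of 76.8% ± 2.23 (SD, n = 3 pairs). Circular shifts of the same summits gave at most 2.26% (permutation p = 0.000999 for each pair, the smallest that 1000 shifts can give). Of the 7241 IDR summits, 4896 or 67.6% (95% interval 66.5 to 68.7) had a summit among the strongest 7241 of all 3 replicates, and 40 had none in those of any. The share was 81.8% for replicate 1, 80.8% for replicate 2 and 93.2% for replicate 3. The order of sites was shared in part: across matched IDR summits, Spearman's rho between signal values was 0.773 for replicates 1 and 2, 0.803 for replicates 1 and 3 and 0.753 for replicates 2 and 3, over 6634, 6944 and 6774 sites that are not independent of each other.

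**Figure D1:**
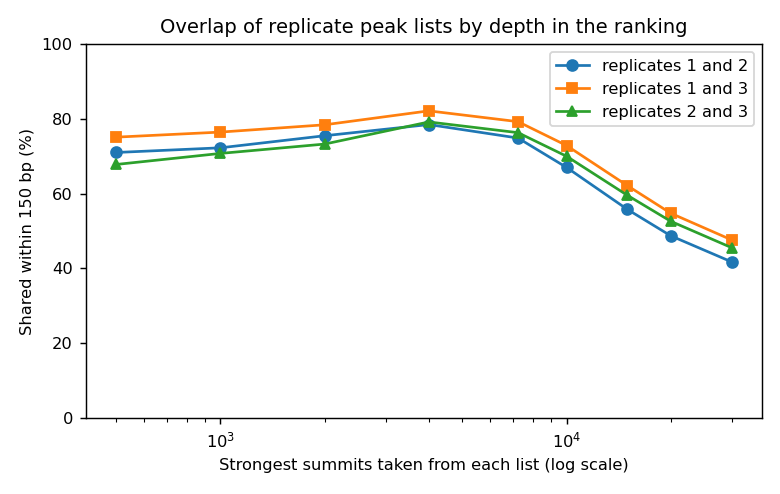
Overlap of the 3 pairs of replicate lists (percent of summits shared within 150 bp, vertical axis) against the number of strongest summits taken from each list (log scale). Each line is 1 pair; overlap was 67.8 to 75.1% at 500 summits, 78.5 to 82.1% at 4000 and 41.8 to 47.6% when all 30000 were taken.

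The 12 strongest peaks were found in every replicate. The highest peak, with a signal value of 17416, had its summit on 2R at 19141539, 93 bp from a TSS of ena (FBgn0000578), which encodes the actin regulator Enabled, and ranked 1 in each replicate. The next, with a signal value of 13600, lay at 6151462 on 2R in an intron of the ecdysone receptor gene EcR (FBgn0000546), 5667 bp from its nearest TSS, and ranked 2 in each replicate. Prosbeta7 (FBgn0250746), a subunit of the 20S proteasome, followed with 9097 at 5358236 on 3R, 61 bp from its TSS. The gene of the tagged protein, stwl (FBgn0003459), held the peak of rank 4, with a signal value of 8792 and a summit at 14409530 on 3L, 409 bp from its TSS and inside the gene. That peak spanned 14408288 to 14411335, at 3048 bp the widest of the IDR list, and ranked 3, 6 and 3 in replicates 1, 2 and 3. Because the line carries a tagged copy of this gene, reads at this locus can come from the transgene as well as from the native gene.

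The other 8 of the 12 strongest peaks lay at promoters in 5 cases. These were CG34345, PIG-B, a mannosyltransferase of GPI anchor synthesis, epsilonCOP, a subunit of the COPI vesicle coat, the Polycomb group gene Scm and the zinc finger gene crol, with signal values of 8595, 6769, 4842, 4752 and 4701. The remaining 3 lay away from promoters. One was intergenic at 16004207 on 3R, 4898 bp from the TSS of GATAe, a GATA factor of the gut. Another at 6709074 on 3R lay 4990 bp from the cuticle protein gene Ccp84Aa, in an intron of the Hox gene pb, and the last at 835032 on 4 lay 639 bp from Sox102F. All 12 peaks ranked among the first 14 in every replicate.

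Binding was concentrated just upstream of TSSs. Of the 7241 IDR summits, 4928 or 68.1% lay within 500 bp of a TSS, where 13.4% of the known bases lie, a fold of 5.07 (95% interval 4.99 to 5.15; two-sided exact binomial test, p below 1e-300). Of the promoter summits, 85.0% (83.9 to 85.9) lay upstream of the nearest TSS. Promoter summits also had the higher signal values, with a median of 465.5 against 325.4 at the other 2313 summits (permutation test, p = 1e-05, the smallest that 100000 resamples can give). Away from promoters, 1239 summits lay in introns, 791 between genes, 169 in 3' UTRs, 48 in coding exons and 35 in 5' UTRs outside the promoter window. Coding exons held 0.0482 times the share expected from their bases (0.0356 to 0.0638). The fold at promoters was 8.45 for a distance of 250 bp and 3.17 for 1000 bp, and the odds ratio against lower-ranked pooled peaks was 7.84.

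**Figure D2:**
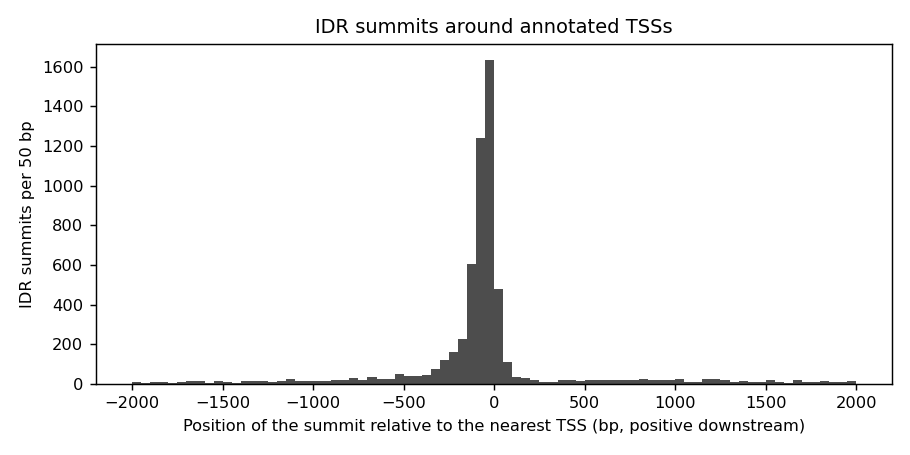
Number of IDR summits per 50 bp (vertical axis) by position relative to the nearest annotated TSS (horizontal axis in bp, negative values upstream). Summits gather directly upstream of the TSS: 4187 of the 4928 summits within 500 bp lie on that side.

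Head-to-head promoters were bound far more often than isolated ones. Of 2667 pairs of protein-coding genes with divergent TSSs up to 1000 bp apart, 1979 or 74.2% had an IDR summit, against 1351 of 5471 isolated genes or 24.7%, an odds ratio of 8.77 (7.89 to 9.76; two-sided Fisher's exact test, p below 1e-300). A pair offers a wider target than a single gene. Each gene was also scored by a summit within 250 bp of its own TSSs, a test chosen after seeing the data. Of genes in such pairs 62.7% were bound and of isolated genes 22.6%, an odds ratio of 5.76 (5.29 to 6.27). A summit between close divergent TSSs still counts for both genes of a pair, so this scoring does not remove the wider target. Paired genes are therefore not independent, and the interval does not allow for that. In the stricter part of the IDR list the odds ratio of pairs was 5.70.

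Ribosomal protein genes were bound at most of their promoters, and chemoreceptor and cuticle protein genes at few. Across the genome 5870 of 13945 protein-coding genes, or 42.1%, had an IDR summit within 500 bp of a TSS. Of the 20 lists, 7 were bound more often than other genes, 6 less often, and 7 did not pass the threshold (two-sided Fisher's exact tests adjusted over the 20 lists). Mitochondrial ribosomal protein genes led with 62 of 73 bound (84.9%; odds ratio 7.83, 4.12 to 14.9; adjusted exact p = 2.78e-13), among them mRpS10, mRpS2 and mRpS23 with signal values of 1820, 1272 and 1143. Cytoplasmic ribosomal protein genes had 71 of 87 bound (odds ratio 6.17, 3.58 to 10.6; adjusted exact p = 2.78e-13), with the strongest promoter peaks at RpL14 (1812), RpL7 (1650) and RpL23A (1495). Proteasome subunit genes had 32 of 48 bound (odds ratio 2.76, 1.51 to 5.04; adjusted exact p = 0.00264). After Prosbeta7, Rpn6 and Rpn9 of the regulatory particle held peaks of 1272 and 1221. The call on proteasome genes ended among isolated genes, a restriction chosen after seeing the data (4 of 13 bound, odds ratio 1.36, adjusted exact p = 0.671), and in the stricter part of the IDR list (2.03, 0.0624). The odds ratios of the ribosomal and mitochondrial ribosomal lists fell to 3.09 and 3.37 in the stricter part, both past the threshold, and that of the mitochondrial list was 4.53 in the consensus of the 3 replicates, 4.47 without replicate 2 or 3 and 15.3 among isolated genes.

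Genes of insulator proteins, silencing factors and the cell cycle were bound at most of their promoters too. Genes of insulator proteins, which partition chromatin into domains, had 16 of 20 bound (odds ratio 5.51, 1.84 to 16.5; adjusted exact p = 0.00301), and the strongest peaks lay at lolal (1047), Chro (1029) and Cp190 (862.2). Heterochromatin and silencing factors had 15 of 19 bound (odds ratio 5.17, 1.71 to 15.6; adjusted exact p = 0.00369). They included the histone methyltransferase gene G9a (1189) and Su(var)3-7 (757.1). Cell cycle genes also had 15 of 19 bound, with the same odds ratio and adjusted exact p, and Cdk4 (1629), CycB (1285) and Cdk2 (861.1) had the strongest peaks. Of Polycomb group genes 12 of 18 were bound (adjusted exact p = 0.0706), with values of 4752 at Scm, 1687 at esc and 1178 at ph-p, and of Trithorax group genes 10 of 15 (adjusted exact p = 0.0839), with 1170 at fs(1)h, 1048 at ash2 and 1026 at skd. Neither passed the threshold, but both did in the consensus of the 3 replicates (odds ratios 3.05 and 3.88, adjusted exact p of 0.0304 and 0.0215), as did the Trithorax list in each consensus without 1 replicate (3.48 to 4.61) and the Polycomb list in that without replicate 1 (3.48). Within 250 bp of a TSS the Trithorax list passed (3.29, adjusted exact p = 0.0468) and the Polycomb list did not (2.59, 0.0685). Among isolated genes neither passed, with 1.22 for Polycomb (adjusted exact p = 0.781) and 6.11 for Trithorax genes (0.339). The esc summit also lies inside the gene Pde1c, and that of ash2 had no match within 150 bp in the list of replicate 2. In the stricter part of the IDR list the insulator and cell cycle lists lost their calls, with odds ratios of 2.61 and 2.35 and adjusted exact p of 0.0827 and 0.109. Among isolated genes, of which the insulator list has 3 and the heterochromatin list 1, their calls were lost with so few genes (adjusted exact p of 0.339 and 0.380) although the odds ratios were higher, at 6.11 and 9.15. Past the threshold each time, the odds ratio of the heterochromatin list was 3.32 in the consensus of the 3 replicates, 2.98 without replicate 1, 3.07 without replicate 3 and 21.6 within 1000 bp of a TSS, and that of the insulator list was 3.60 in the consensus and 10.8 within 1000 bp, while that of the cell cycle list was 21.5 among isolated genes.

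Germline genes were bound at 18 of 24 promoters (odds ratio 4.14, 1.64 to 10.4; adjusted exact p = 0.00369). The list includes stwl, where reads can come from the transgene. Without summits within 50 kb of stwl, an alternative chosen after seeing the data, the odds ratio was 3.35 (adjusted exact p = 0.01345). Besides stwl itself, the RNA-binding protein gene Rbfox1 (2368) and the germline gap junction gene zpg (1957) had the strongest peaks. The zpg summit, 77 bp from its TSS, also lies inside the gene Rexo5. The differentiation factor gene bam (FBgn0000158) was bound as well, with a signal value of 760.0 at 25245603 on 3R, 494 bp from its TSS and thus close to the limit of 500 bp, and ranks of 3991, 2632 and 901 in replicates 1, 2 and 3. Testis differentiation genes, by contrast, were bound at 4 of 25 (odds ratio 0.262, 0.0897 to 0.762; adjusted exact p = 0.0155). Their strongest peaks lay at bol (688.7), mia (477.6) and twe (384.9), of which twe also stands in the cell cycle list. Among isolated genes, which are fewer, neither call held although the odds ratios were alike, with 5.10 for 5 of 8 germline genes (adjusted exact p = 0.0861) and 0.234 for 1 of 14 testis genes (0.352). The testis call was also lost in the stricter part of the IDR list (odds ratio 0.226, adjusted exact p = 0.0624) and within 1000 bp of a TSS (0.377, 0.0605). Both lists kept their calls within 250 bp (2.75 and 0.143), and the odds ratio of the germline list was 6.36 in the stricter part.

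Hox, pair-rule, mesoderm, chemoreceptor and cuticle protein genes were bound less often than other genes. None of the 8 Hox genes had a promoter summit (upper Wilson limit 32.4%; adjusted exact p = 0.0376), Abd-B and Antp included. Of 12 pair-rule genes only hry had one, with a signal value of 221.3 (adjusted exact p = 0.0303), and of 13 mesoderm and muscle genes only Mef2, with 543.3 (adjusted exact p = 0.0195). Odorant and gustatory receptor genes had 6 of 179 bound (odds ratio 0.0467, 0.0207 to 0.106; adjusted exact p = 2.48e-32), with 823.4 at Ir60e, 659.7 at Gr63a and 254.7 at Gr61a. The Gr61a summit had no match within 150 bp in the list of replicate 2. Cuticle protein genes had 1 of 115 bound, Lcp9 with 372.4 (odds ratio 0.0119, 0.00166 to 0.0852; adjusted exact p = 4.36e-25). The Hox, pair-rule and mesoderm calls were lost in the stricter part of the IDR list, where fewer genes are bound (odds ratios 0.153, 0.104 and 0.217; adjusted exact p of 0.145, 0.0827 and 0.152), and among isolated genes, where fewer are tested (0.203, 0.277 and 0.132; adjusted exact p of 0.352, 0.420 and 0.218). In the consensus of the 3 replicates the Hox and mesoderm calls were lost (0.114 and 0.161; adjusted exact p of 0.0678 and 0.0775). The Hox call was also lost without replicate 3 (0.105; adjusted exact p = 0.0636) and the pair-rule call within 250 bp of a TSS (0.149; 0.0539). The mesoderm call was lost without replicate 1 (0.316; adjusted exact p = 0.160), without replicate 3 (0.149; 0.0541) and within 1000 bp (0.217; 0.0625). The pair-rule call held in the consensus (0.0773) and without any 1 replicate (0.0668 to 0.0715). The odds ratio of receptor genes was 0.0215 in the consensus and 0.0192 without replicate 1, and over all alternatives it ran from 0.0151 to 0.0766 and that of cuticle genes from 0.00703 to 0.0287, each past the threshold.

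The other developmental lists did not pass the threshold. Gap and terminal genes had 2 of 12 bound (adjusted exact p = 0.100), bcd, the anterior determinant, with 1493 and Kr with 253.9. Segment polarity genes had 5 of 12 (adjusted exact p = 1), with 731.4 at smo, 309.2 at wg and 283.9 at fz. Dorsoventral genes had 4 of 21 (adjusted exact p = 0.0630), with 726.2 at cact, 585.5 at tin and 250.1 at sog. Neurogenic genes had 5 of 18 (adjusted exact p = 0.256), with 488.0 at Delta, 463.8 at elav and 430.3 at numb. Gut and fat body genes had 1 of 8 (adjusted exact p = 0.167), pnt with 257.5. The summits of smo, elav and Kr also lie inside other genes, namely CG17078, arg and CG9380. Those of Delta and pnt had no match within 150 bp in the list of replicate 2. The odds ratio of segment polarity genes was 0.983, and it was 0.387 in the consensus of the 3 replicates, 0.334 without replicate 2, 0.358 without replicate 3 and 0.237 in the stricter part, none past the threshold. That of gap genes was 0.275, and it was 0.176 in the consensus, 0.158 without replicate 1 and 0.163 without replicate 3, none past the threshold. In the same consensus dorsoventral and neurogenic genes were bound less often than other genes (odds ratios 0.203 and 0.114, adjusted exact p of 0.0276 and 0.0215), and so were dorsoventral genes without any 1 replicate (0.183 to 0.278), neurogenic genes without replicate 1 or 3 (0.217 and 0.105) but not without replicate 2 (0.334, adjusted exact p = 0.0971). Gut and fat body genes missed the threshold in the consensus (0.114, adjusted exact p = 0.0678) and without replicate 3 (0.105, 0.0636), and passed it without replicate 1 (0.102, 0.0365) and without replicate 2 (0.0983, 0.0447). Among isolated genes, a restriction chosen after seeing the data, the odds ratio of neurogenic genes was 0.938, from 0.529 among all genes. There it was 0.609 for gap, 0.406 for dorsoventral and 0.203 for gut and fat body genes, none past the threshold.

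**Figure D3:**
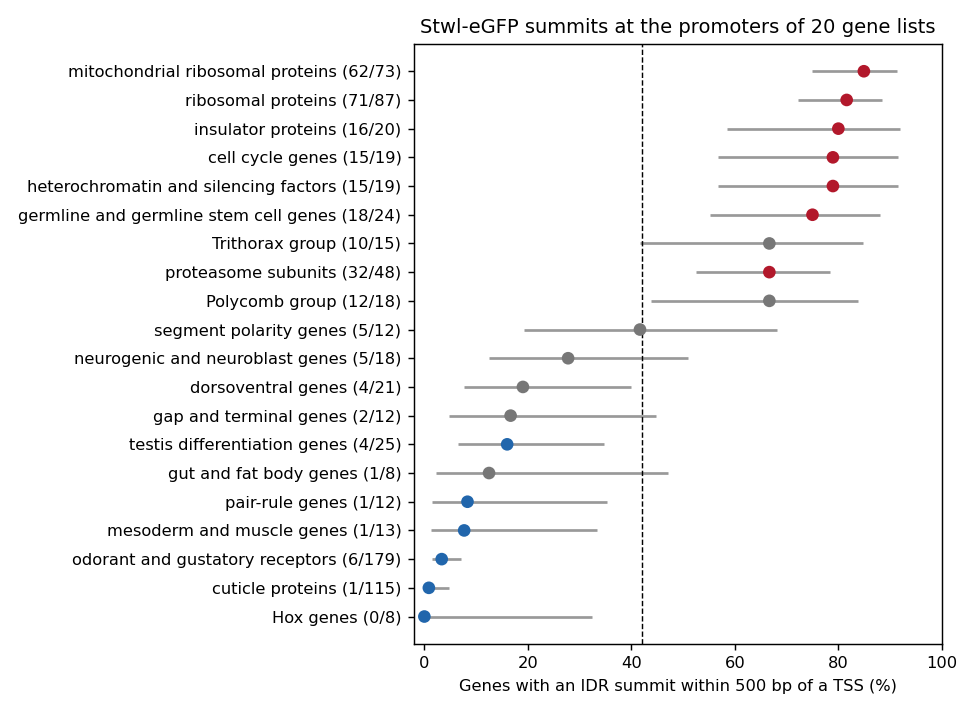
Percent of genes in each of the 20 lists with an IDR summit within 500 bp of a TSS (points, with 95% Wilson intervals; bound and total genes in brackets). Red points passed the adjusted threshold above other genes and blue points below; grey points did not pass, and the dashed line marks the 42.1% of all protein-coding genes.

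Genes for non-coding RNAs were bound less often than protein-coding genes in all 5 classes tested. The share was 9.97% for long non-coding RNA genes (244 of 2447; odds ratio 0.152, 0.133 to 0.175), 8.28% for tRNA genes (24 of 290; 0.124, 0.0816 to 0.189), 5.95% for snoRNA genes (16 of 269; 0.0870, 0.0524 to 0.144) and 15.6% for snRNA genes (5 of 32; 0.255, 0.0980 to 0.662). None of 99 rRNA genes was bound. The highest adjusted exact p of the 5 was 0.00198, for snRNA genes, and multi-copy classes are uncertain because reads from their copies may not have been placed. The odds ratio of snRNA genes was 0.0401 in the stricter part of the IDR list, 0.129 in the consensus of the 3 replicates, 0.112 without replicate 2 and 0.119 without replicate 3.

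Summits were sparse in sequence near centromeres and in transposable elements, where heterochromatin lies. Centromere-proximal parts of 2L, 2R, 3L, 3R and X held 69 summits or 3.84 per Mb, against 62.3 per Mb in the rest of these arms, a fold of 0.0616 (0.0479 to 0.0781; two-sided exact binomial test, p below 1e-300). Chromosome 4, which is mostly heterochromatic, held 44 summits or 33.1 per Mb against 53.6 on the large autosome arms (fold 0.617, 0.448 to 0.829; adjusted exact p = 0.00159). Only 21 summits (0.290%) lay in annotated transposable elements, which take 5.94% of bases (fold 0.0488, 0.0302 to 0.0746; exact binomial test, p = 7.62e-157), with folds of 0.0233 in the stricter part of the IDR list, 0.0274 in the consensus of the 3 replicates and 0.0304 without replicate 1. Repeats where reads cannot be placed hold no peaks, and against lower-ranked pooled peaks, which face the same limit, the odds ratio in proximal sequence was 0.518 (0.401 to 0.670), while moving the boundaries 1 Mb gave folds of 0.0179 and 0.202. All these comparisons are per base or per peak and were not adjusted for the number of promoters. Promoters hold 68.1% of IDR but 21.4% of lower-ranked summits, so whether promoters in these regions are bound less often was not tested. On X the density was 58.2 per Mb, a fold of 1.09 (1.02 to 1.15; adjusted exact p = 0.00575), but in the stricter part of the IDR list X lay below the autosome arms (fold 0.807, adjusted exact p = 6.65e-06), and the call was lost in the consensus of the 3 replicates (1.03, adjusted exact p = 0.369), without replicate 1 (1.04, 0.238) and without replicate 3 (1.05, 0.170).

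Sequences of known promoter and insulator elements were frequent at summits. The DNA replication-related element (DRE, TATCGATA), bound by Dref, occurred within 100 bp of 870 summits or 12.01% (11.3 to 12.8), against 0.601% of flanks. Motif 1 (YGGTCACACT), the site of M1BP at promoters of ribosomal protein and other general genes, was at 7.97% against 0.249%. Paired CGATA, copies of the core of the BEAF-32 site up to 40 bp apart on either strand, was at 23.8% against 2.04%. A DRE reads as CGATA on both strands. All 870 windows with a DRE are therefore among the 1722 with paired CGATA, and the 2 motifs are not separate results. The CTCF core was at 3.29% against 0.511% and the Su(Hw) core at 1.48% against 0.228%. The E-box CAGCTG and the TATA box were raised less, at 14.0% against 10.6% and 29.9% against 19.5%. Adjusted p was at most 7.54e-09 for these 7 motifs (exact McNemar tests against the upstream flank, adjusted over 12 motifs). At least 1 of the DRE, Motif 1, paired CGATA, CTCF and Su(Hw) cores was present at 34.3% of summits and 2.91% of upstream flanks. The folds of the DRE and Motif 1 were 20 and 32.1 against flanks, 9.49 and 19.5 against lower-ranked pooled peaks, and 38.2 and 55.1 in the stricter part of the IDR list. Against lower-ranked peaks those of paired CGATA and the CTCF core were 6.34 and 3.07, from 11.7 and 6.43, and the fold of the Su(Hw) core was 4 in the consensus of the 3 replicates and without replicate 1 and 4.13 without replicate 3, from 6.48, each past the threshold.

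Sites of Zelda and Twist were less frequent at summits than in flanks. The site of Zelda, the pioneer factor of zygotic genome activation, fell below the flanks, at 0.594% against 1.33% (adjusted exact p = 6.17e-05), and the E-box of Twist was at 8.30% against 9.50% (adjusted exact p = 0.0431), a fold of 0.874. That fold was much the same within 50 bp of the summit and with a single summit per interval, at 0.878 and 0.874, but not past the threshold (adjusted exact p of 0.201 and 0.0663). The Pho site was at 6.49% against 7.42% (adjusted exact p = 0.140) and the initiator at 17.5% against 16.5% (adjusted exact p = 0.101). The flank tested held the Pho site at 7.13% and the other flank at 7.71%. The GAGA repeat was at 8.38% against 7.46% (adjusted exact p = 0.0274), but it lay below lower-ranked pooled peaks (fold 0.837, adjusted exact p = 5.15e-05), and the folds were 0.919 in the consensus of the 3 replicates and 0.927, 1.00 and 0.899 without replicates 1, 2 and 3, none past the threshold. Against lower-ranked peaks the Su(Hw) core was no longer raised (fold 1.16, adjusted exact p = 0.194) and the Pho site lay lower (fold 0.826, adjusted exact p = 0.000121). Against promoters without a peak, a background chosen after seeing the data, the TATA box and the initiator lay lower at promoter summits (folds 0.879 and 0.469), the Twist E-box higher (fold 1.23, adjusted exact p = 0.00544), and the Su(Hw) core was not past the threshold (2.24, adjusted exact p = 0.0550). The background windows were centred on the TSS and the others on the summit, at a median of -53.5 bp from the TSS. Window placement alone can change the share of a motif tied to the TSS, so these folds cannot be credited to bound promoters.

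**Figure D4:**
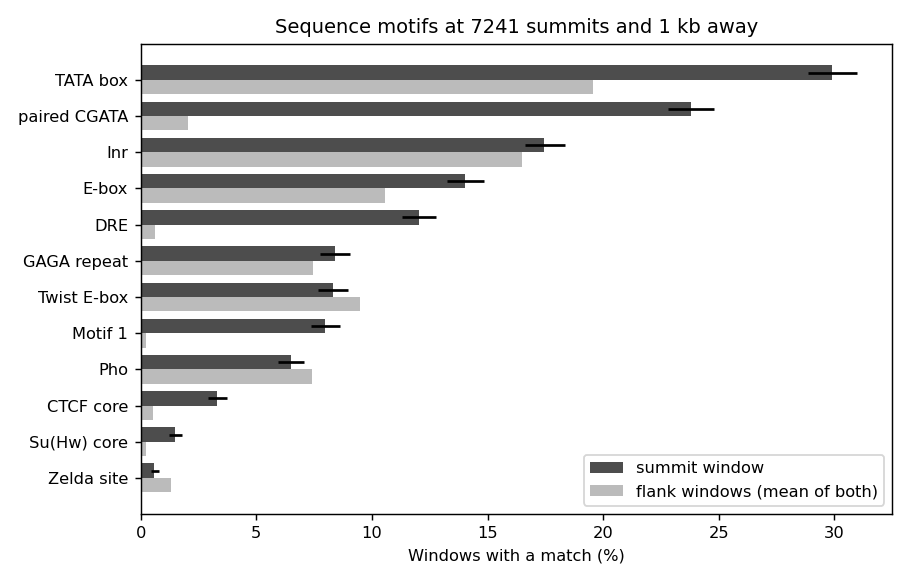
Percent of windows with a match (horizontal axis) for 12 motifs within 100 bp of 7241 IDR summits (dark bars, with 95% Wilson intervals) and in flank windows centred 1000 bp away (light bars, mean of both sides). Motif 1, the DRE and paired CGATA differ most from their flanks by fold (32.1, 20 and 11.7).

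A search over all 32896 strand-collapsed 8-mers ranked sequences of the DRE and Motif 1 first. TATCGATA led, at 12.01% of summit and 0.601% of flank windows (adjusted exact p below 1e-300), followed by the Motif 1 sequence GGTCACAC at 11.2% against 0.559% (adjusted exact p = 2.16e-292). Sequences outside the fixed list included CAACACTG, at 6.56% against 0.621% (adjusted exact p = 7.40e-137), and AAAATACC, at 5.80% against 1.24% (adjusted exact p = 4.16e-74); both were chosen after their values were seen. In all 3412 8-mers were more frequent at summits and 6439 less frequent. Summit windows had a GC content of 38.0% and upstream flanks 44.1%, and neither the 8-mer counts nor the tests of the 12 motifs against flanks were adjusted for this.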

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

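Both results of this part concern the 22756 pooled-list summits on the main arms that did not pass the IDR threshold, which the comparisons above use only as a background, and the tests on them were chosen after seeing the data. Of these summits, 14.3% had a summit within 150 bp in all 3 replicate lists, or 3257 sites, while circular shifts gave at most 0.101%. The pooled list comes from the same 3 libraries, so this shows recurrence beyond random placement and not specific binding. The promoter share of lower-ranked summits was 21.4%, against 68.1% in the IDR list.

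The density of these lower-ranked summits on X was 1.63 times that on the large autosome arms (95% interval 1.58 to 1.68), while the fold in the IDR list was 1.09. Summits below the strongest 7241 of each replicate list gave folds of 1.31, 1.37 and 1.53 in replicates 1, 2 and 3, a mean of 1.40 ± 0.112 (SD, n = 3), so X was higher in 3 of 3 replicates. The −log10 q-value fell to 0.294 in the pooled list, against a lowest value of 3.66 in the IDR list, so peaks of low confidence are included. A background on X could recur in every replicate list, and whether background or binding gives these folds was not tested.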

How the results depend on the processing

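Of 474 alternative values, 119 concern a main result: 105 kept their direction and side of the threshold, or for a count stayed within 1.5 times; the restriction to isolated genes, the 50 kb exclusion around stwl, the single summit per interval, the 250 bp test of head-to-head genes and the promoters without a peak were chosen after seeing the data. The fold on X was 0.807 in the stricter part of the IDR list, 1.03 in the consensus and 1.04 to 1.07 without 1 replicate, which is also a consensus; the cause was not tested. The number of lists bound more often was 4 in the stricter part and 3 among isolated genes, against 7, and of those bound less often 2 in both, against 6; both alternatives leave fewer bound or fewer tested genes. With 6-mers 599 sequences were raised, out of fewer possible ones. IDR summits found in all replicates were 47.0% within 50 bp, 73.0% within 300 bp and 70.9 to 77.5% without 1 replicate, which asks for fewer matches. The fold of the GAGA repeat was not past the threshold at 0.847 in the stricter part, 0.919 in the consensus, 0.899 to 1.00 without 1 replicate and 0.980 within 50 bp, and it was past the threshold, below the background, at 0.837 against lower-ranked peaks and 0.783 against promoters without a peak. The initiator, which had not passed the threshold, had folds of 0.926, 0.979, 0.931 to 1.02, 0.948 and 0.469 in the same order, leaving aside the 50 bp window. Against promoters without a peak the TATA box was at 0.879 and the Twist E-box at 1.23. All folds against that background, those of the GAGA repeat and the initiator included, compare windows centred on summits with windows centred on TSSs. Segment polarity genes, never past the threshold there, had odds ratios of 1.18 at 250 bp and 1.31 among isolated genes. The cause of these changes was not tested. Among single lists, classes and motifs, 292 values kept their call, 28 lost it, 18 gained it and 17 turned direction. Promoter share, proximal density, chromosome 4, head-to-head promoters, RNA gene classes, transposable elements and signal by location kept direction and call in each alternative run for them; signal differences of 14.97 to 26.2 in the consensus sets are on the scale of a replicate list. Leaving out summits within 50 kb of stwl gave a promoter fold of 5.08. No paired analysis was possible because there is only 1 group. Read depth is unknown, so whether sites missing from a replicate are absent or below its detection limit was not tested.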

Other observations

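The tests on the weight of the replicates, their overlap and the stwl locus were chosen after their results, or values close to them, had been seen; the others had their predictions written first. Summits away from promoters held known motifs at other shares than promoter summits. Among the 1876 IDR summits more than 1000 bp from any TSS, the Su(Hw) core occurred at 3.94% against 0.365% of promoter summits, 10.8 times as often (Fisher's exact test, adjusted exact p = 9.55e-26 over 12 motifs), and the CTCF core at 6.34% against 1.95%, 3.26 times as often (adjusted exact p = 9.39e-18). The DRE went the other way, at 2.99% against 16.1%, a ratio of 0.186 (adjusted exact p = 4.39e-59). Motif 1 was at 4.42% of distal and 9.88% of promoter summits, and the GAGA repeat at 11.99% and 6.72%. Against their own flanks, distal summits had folds of 23.7 for Motif 1, 13.2 for the CTCF core, 11.4 for the Su(Hw) core, 6.59 for the DRE and 4.15 for paired CGATA (7.20% of distal summits), which were not tested. The paired CGATA share includes every window with a DRE.

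A hypothesis that patterning genes (the gap, pair-rule, segment polarity, Hox and dorsoventral lists) without an IDR promoter summit are bound below the threshold could not be decided: 10 of 53 had a lower-ranked summit within 500 bp, against 1945 of 8022 other genes (odds ratio 0.727, with an interval from 0.364 to 1.45 that leaves both directions open; Fisher's exact test, p = 0.424). Outside these lists, and counting genes with and without an IDR summit, neurogenic genes had a lower-ranked promoter summit at 11 of 18 (odds ratio 4.42, 1.71 to 11.4; exact p = 0.00959, adjusted over 20 lists), as did lists that are not developmental, with 12 of 19 cell cycle genes (4.82; 0.00522) and 13 of 24 germline genes (3.33; 0.0160), and among the lists of the hypothesis the odds ratios ran from 0.165 for Hox to 2.81 for segment polarity genes, none past the threshold. A second hypothesis, that the bithorax complex holds many summits away from its promoters, was contradicted. The 315.6 kb from Ubx to Abd-B (3R, 16656623 to 16972236) held 1 IDR summit, a density 0.0583 times that of the rest of the genome (0.00148 to 0.325; exact binomial test, p = 1.31e-06). The density of the rest counts promoter summits, which are 68.1% of the IDR list. The fold and p are therefore not those of summits away from promoters alone.

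The DRE was far more frequent at summits than in flanks. Composition shared by all promoters would give bound and unbound promoters the same share, but 18.5% of 5870 genes with an IDR promoter summit and 2.01% of 6120 genes with no pooled-list summit there had a DRE within 250 bp of the TSS, genes with lower-ranked summits left aside, an odds ratio of 11.07 (9.15 to 13.4). A feature of weak peaks is contradicted too: the DRE was at 17.7% of the 1810 strongest and 5.80% of the 1811 weakest IDR summits, 3.05 times as often. Whether these promoters are recovered with any antibody because their chromatin is open was not tested, since the control library was not analysed here. The comparison of bound and unbound promoters also does not address a composition particular to some classes of promoters. No biological explanation was tested.

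IDR summits were matched best by replicate 3. At the 6581 sites matched in all 3 lists, replicate 3 made up a median of 66.4% of the summed signal values, and the sum was 1.00 times the pooled value in the median, so the pooled ranking may rest mostly on this library. That replicates 1 and 2 are more like each other than like replicate 3 is argued against for replicate 1. At every number of summits taken it shared more with replicate 3 than with replicate 2. The shares were 79.2% against 74.9% at 7241 summits and 78.4% against 75.5% at 2000. For replicate 2 it cannot be told. At 7241 summits its overlap with replicate 1 differed from that with replicate 3 by -1.44 percentage points, but at 2000 it was 75.5% against 73.3%. No biological explanation was tested.

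The peak at stwl ranked 4, and a fault of a single library is contradicted, since its lowest place in the 3 replicates was 6. Extra copies of a cloned fragment could raise the region: 42 pooled-list summits lay within 20 kb, at the 99.92 percentile of IDR promoter summits, and 25.8 per 40 kb were found 100 to 200 kb away. The sides had 32 and 19.6 per 40 kb, below the 42 near stwl but above the 75th percentile of 19, by less than counting error on 1 side, so whether the excess is limited to the surroundings of stwl is open. The 16 IDR summits 2 to 50 kb away had a median signal value of 283.5, below the 416.0 of all IDR summits, which decides nothing where weak peaks are in excess. The size of the insertion and the coverage were not used here, so extra copies and binding at the native gene cannot be told apart.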
